A study of Mus musculus with 96 samples.

How the data were processed

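Total RNA of striatum and cortex was sequenced from 48 mice on a C57BL/6 background at 6 months of age, 8 animals (4 females and 4 males) for each of 6 genotypes and both tissues from every animal, 96 libraries in all. Libraries were made with a stranded TruSeq kit from RNA purified on RNeasy columns, per the labels' protocols. The series text gives a larger number per group than the labelled animals of 1 tissue; the labels were followed here. Counts of genes and p-values take the animals as independent within a tissue, although animals that share the first number of their code correlated by 0.133 in striatum and 0.131 in cortex; the tissues share their animals. The code of an animal has 2 numbers; the meaning of the first is not given in the sources used here. All Pms1 null and Q140 Pms1 null animals have a first number of 16 or more (late codes), against 2 WT, 3 Q140, 0 Pms1 het and 1 Q140 Pms1 het animals.

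The deposited count table holds whole-number read counts per gene and library, not normalized, as its values show. Per the submitters' processing notes, STAR 2.7.5c, SAMtools 1.10, HTSeq 0.12.3 and the mouse builds GRCm38 and mm10 were named, with no role or order given. The strand setting of the counting and the annotation release are not given in the sources used here, so genes that overlap another or lie antisense to one, such as Tsix, are uncertain, as are near-identical family members such as protocadherins, histones and ribosomal proteins. A second deposited table holds FPKM values by the authors; in every library they were the counts rescaled by gene and library, with 0 genes departing by more than 1 in 1000. The table lists 48795 genes, of which 48435 have an identifier in GENCODE release M21, which gave the coordinates on GRCm38; 126 names occur more than once. Library totals lay between 27993751 and 56364535 counts, and the 10 most abundant genes took 5.12% to 8.02% of a library.

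Libraries were compared before they were averaged. All 96 fell with their labelled tissue and sex. Among 144 pairs of libraries of 1 genotype, tissue and sex, the lowest chi-square per degree of freedom was 3.55 (median 8.66) and the highest correlation 0.996, so no pair differed by sampling noise alone and none was merged.

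Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts (TMM scaling, filterByExpr by genotype, quasi-likelihood fit with robust settings), in 1 fit per tissue over its 48 libraries with genotype and sex as terms. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, and adjusted p-values in the text are edgeR's unless another test is named. The comparisons were Q140, Pms1 het and Pms1 null against WT, Q140 Pms1 het and Q140 Pms1 null against Q140, and each of these against its own Pms1 genotype. The difference of the knock-in effect between Pms1 backgrounds, sexes and tissues was tested as a contrast in the fit. CPM values are scaled with TMM factors, and log2 fold changes are edgeR's. The test of the tissues used all 96 libraries with sex by tissue terms. Because both tissues came from the same animals, it was repeated with the animal as a block. As a check of the pairing, the deviations of the 48 pairs from their group means had a median correlation of 0.115 (lowest 0.0395, 32 above 0.1); in 42 pairs the library correlated best with its own animal.

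Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists held MSN, other cell-type, signalling, stress, repair and housekeeping genes. Each was tested with limma 3.58.1's fry, adjusted over the 31 lists with measured members. Each was tested again with camera and an estimated correlation, which compares a list with all other genes. Named genes were Pms1 and Htt; the genes with the largest increase and decrease among called genes with a mean of at least 1 CPM, a name other than a predicted-gene name and the same direction in both sexes (10 each way for striatal Q140 against WT, 5 otherwise); and up to 3 risen and 3 fallen members of each list. The direction in each sex came from a fit with a term for every genotype and sex. A selection of these genes is printed, and some that the rule names are not reported here.

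The signature score of an animal was the mean of direction times log2 CPM (prior count 2) over genes called for Q140 against WT in the other sex alone, 2804 genes for scoring females and 4012 for males in striatum. It was scaled to WT mean 0 and Q140 mean 1 within each sex. Scores were compared by exact permutation within sex (4900 arrangements, two-sided, smallest possible p 0.000408), adjusted over 14 tests, which treats animals that share the first number of their code as independent, and the retained share had a percentile interval from 10000 bootstrap resamples of animals. In cortex too few genes passed (1 and 7), the 100 genes with the smallest p were used, and the score was left unscaled because Q140 and WT did not differ on it. Calls within 5 Mb of Pms1 or Htt were compared with those elsewhere by Fisher's exact test, adjusted over 28 tests. Genes that moved back with Pms1 loss were counted also after 10 random splits of the Q140 libraries and in 5 simulated sets without a Pms1 effect.

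Alternatives were RLE size factors, DESeq2 1.42.0, no filter, a filter of 1 CPM in 8 libraries, only the 2 genotypes compared, no sex term, a term for early or late codes, limma voom with the correlation of animals that share the first number, each sex alone, limma on log2 FPKM with pseudocounts of 1 and 0.1, and other signature genes (50, 500, or chosen in all animals). Chosen after the data were seen were the fits of early or late codes alone, the fits without libraries that stood apart (striatum of animals 14-4 and 44-1, cortex of 7-3, 22-3 and 17-2), a glucocorticoid gene score as a covariate, that score without 5 of its genes and with animals of 1 first number averaged, and the unscaled cortical score. Groups were also redrawn in 100 splits, tested with limma on log2 CPM.

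The methods were tested on simulated counts with 200 changed genes. In the striatal simulation edgeR called 58.2% of the genes changed by 1.25-fold, 82.1% at 1.5-fold and 90.9% at 2-fold. It also called 6 unchanged genes, with 18763 genes tested in all. In the cortical simulation it called 67.2%, 85.1% and 89.4%, and 8 unchanged genes, with 18599 genes tested in all. For the tissue difference, 180 of 200 changed genes and 8 unchanged genes were called, with 17975 genes tested in all. Simulated retained shares of 0.5 and 1 were returned as 0.508 and 0.998.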

Results

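RNA was sequenced from the striatum and the cortex of 48 mice aged 6 months, 96 libraries in all. The animals belonged to 6 genotypes that combine the Q140 allele with 2, 1 or 0 working copies of Pms1. Q140 is a knock-in allele of Htt, the Huntington's disease gene, that carries an expanded CAG repeat. Pms1 encodes a MutL-family protein of DNA mismatch repair, the pathway that governs how far such repeats lengthen in somatic cells. The genotypes were wild type (WT), heterozygous Q140 (Q140), Pms1 heterozygous (Pms1 het), Q140 with 1 Pms1 copy (Q140 Pms1 het), Pms1 null, and Q140 on a Pms1 null background (Q140 Pms1 null). Each genotype had 8 animals, 4 females and 4 males, and both tissues came from the same animals. Gene counts summed to between 27993751 and 56364535 per library. The design asks what the knock-in does to each brain region, what the loss of Pms1 does on its own, and how far the loss of Pms1 alters the knock-in effect.

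The targeted genes were examined first. Pms1 (ENSMUSG00000026098, chromosome 1, 53189187 to 53297018, GRCm38) was a weakly expressed gene in the striatum, at 5.43 ± 0.34 CPM in WT (SD, n = 8) and 5.24 ± 0.61 CPM in Q140 (SD, n = 8). Its level was 4.54 ± 0.56 CPM in Pms1 het, 4.45 ± 0.64 CPM in Q140 Pms1 het, 4.03 ± 0.44 CPM in Pms1 null and 4.19 ± 0.36 CPM in Q140 Pms1 null (SD, n = 8 each). The null animals thus kept most of the Pms1 RNA counted over the whole gene. The log2 fold change was -0.43 (SE 0.08, adjusted p = 0.000698) for Pms1 null against WT and -0.33 (SE 0.08, adjusted p = 0.0045) for Q140 Pms1 null against Q140. For the heterozygotes it was -0.26 without the knock-in (SE 0.08, adjusted p = 0.29) and -0.25 with it (SE 0.08, adjusted p = 0.755). In cortex, Pms1 stood at 3.78 ± 0.40 CPM in WT and 3.53 ± 0.39 CPM in Pms1 null (SD, n = 8 each), with means from 3.43 to 3.58 CPM in the other genotypes. Between WT and Pms1 null this was a difference that did not pass the test (log2 fold change -0.10, SE 0.08, adjusted p = 0.467). The labels do not describe the Pms1 allele, so the count over the gene is a weak check of the genotype. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) changed little. Its striatal level was 213 ± 6.59 CPM in WT and 203 ± 4.86 CPM in Q140 (SD, n = 8 each; log2 fold change -0.07, SE 0.02, adjusted p = 0.0158), and 216 ± 5.96 CPM in Q140 Pms1 null (log2 fold change against Q140 0.09, SE 0.02, adjusted p = 0.00774). Without TMM scaling Htt had a mean of 208.0 CPM in WT, 208.8 CPM in Q140 and 216.1 CPM in Q140 Pms1 null, so the decrease in Q140 depended on scaling for RNA composition; with RLE size factors its log2 fold change was -0.07.

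The knock-in lowered the genes that define medium spiny neurons (MSNs), the projection neurons that make up most of the striatum. Of 30 pan-MSN genes, 29 fell in Q140 against WT and none rose. Ddit4l, an inhibitor of mTOR signalling, fell by 1.77 on the log2 scale (SE 0.09), Ryr1, a calcium release channel, by 1.04 (SE 0.09), and Scn4b, a sodium channel subunit, by 1.00 (SE 0.06, from 2696 ± 123 to 1348 ± 106 CPM, SD, n = 8 each). Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), the enkephalin precursor of indirect-pathway neurons, fell from 1746 ± 136 to 828 ± 51.0 CPM (SD, n = 8 each; log2 fold change -1.07, SE 0.05, adjusted p = 1.3e-19). Over all genes, edgeR called 5909 of 18890 at an adjusted p below 0.05, 2999 higher and 2910 lower; 606 of them differed by more than 1.5-fold, 314 higher and 292 lower.

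Among the genes with the largest increases in Q140 striatum were Sfmbt2, a Polycomb-related protein (log2 fold change 1.41, SE 0.10), the desmosomal cadherin Dsg2 (1.24, SE 0.22), Fam196b (1.14, SE 0.15), the giant sarcomere protein Ttn (1.14, SE 0.13), Ipcef1 (1.13, SE 0.12), Tnnt2, cardiac troponin T (1.08, SE 0.09), Greb1l (1.07, SE 0.15), Dsg1c, another desmosomal cadherin (1.07, SE 0.21), and Nts, the neurotensin precursor (1.06, SE 0.18). The largest decreases were those of the transcription factor Mafa (-2.23, SE 0.16), Aoah (-2.20, SE 0.24), the Wnt ligand Wnt8b (-2.0, SE 0.30), Cpne9 (-1.86, SE 0.11), the glutathione peroxidase Gpx6 (-1.85, SE 0.14), the immediate early transcription factor Egr2 (-1.84, SE 0.29), Ddit4l, Serpinb1b (-1.56, SE 0.13), Dgat2l6 (-1.56, SE 0.16) and Sec14l3 (-1.50, SE 0.14). Mafa fell from 3.17 to 0.675 CPM and Aoah from 1.75 to 0.372 CPM, whereas Sfmbt2 rose from 2.41 ± 0.33 to 6.44 ± 1.05 CPM (SD, n = 8 each). Wt1, a transcription factor of the developing kidney and gonad, had the largest increase of any gene in the fixed lists, from 0.0904 to 0.745 ± 0.303 CPM (SD, n = 8; log2 fold change 3.02, SE 0.40, adjusted p = 2.4e-08), at a level that corresponds to few counts per library.

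Gene lists fixed before the data were examined were tested with fry, which asks whether the genes of a set move on balance in one direction and does not compare them with other genes. Each was tested again with camera, which compares the genes of a set with all other genes. Camera used a correlation between genes estimated from the data. P-values given below with an estimated correlation are those of camera. Fry keeps the correlation between genes as well, so a call that camera lacks need not be due to correlation alone. Among indirect-pathway markers, 5 of 8 fell and 1 rose (adjusted p = 4.5e-15, and adjusted p = 0.000753 with an estimated correlation). Besides Penk, the fallen genes included Adora2a, an adenosine receptor (log2 fold change -0.70, SE 0.06), and Gpr6 (-0.61, SE 0.05), while P2ry1 rose (0.47, SE 0.15). The 8 direct-pathway markers split, with 3 higher and 3 lower: Drd1 (-0.54, SE 0.04) and Chrm4 (-0.49, SE 0.05) fell, and Isl1 (0.31, SE 0.04) and Tac1 (0.17, SE 0.04) rose. Fry called this list lower (adjusted p = 0.001), but the adjusted p = 0.507 with an estimated correlation. The pan-MSN genes fell with adjusted p = 3.9e-16 (adjusted p = 0.000435 with an estimated correlation). Adjusted over the list alone, the counts for these 3 lists were the same.

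Ion channels and G-protein regulators of MSNs fell in 15 of 18 cases with none higher (adjusted p = 4.7e-14, and adjusted p = 0.00211 with an estimated correlation), among them Rgs14 (log2 fold change -0.90, SE 0.07) and the protein kinase C gene Prkcb (-0.49, SE 0.03). Of 16 glutamate and GABA receptor genes 7 fell and 3 rose (adjusted p = 1.9e-06, but adjusted p = 0.25 with an estimated correlation), and 9 fell and 4 rose adjusted over the list alone. Gabrd fell (-0.49, SE 0.04); Gabra2 also fell (-0.50, SE 0.16), but its level varied in steps between animals of one genotype. Immediate early genes, which neurons switch on when active, fell in 11 of 15 cases (adjusted p = 4.3e-05, but adjusted p = 0.403 with an estimated correlation), including Nr4a1 (-1.07, SE 0.29) and Nr4a3 (-1.04, SE 0.32). Of 7 neurotrophin signalling genes 3 fell, Vgf the most (-0.42, SE 0.10); the adjusted p = 3.7e-09 became adjusted p = 0.108 with an estimated correlation.

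Clustered beta protocadherins, cell adhesion genes arrayed side by side on 1 chromosome, rose in 14 of 22 cases, 15 adjusted over the list alone, and none fell (adjusted p = 9.6e-13, and adjusted p = 0.00503 with an estimated correlation). Pcdhb21 (log2 fold change 0.72, SE 0.07) and Pcdhb3 (0.71, SE 0.08) rose most; these genes resemble each other, so reads may be split among copies. Mismatch repair and repeat-modifier genes rose in 7 of 17 cases, 8 adjusted over the list alone (adjusted p = 1.3e-08, but adjusted p = 0.108 with an estimated correlation). The nuclease genes Fan1 (0.23, SE 0.05) and Exo1 (0.40, SE 0.15) were among them, both by modest amounts. Cholesterol synthesis genes went both ways, with 6 of 20 lower and Tm7sf2 higher (0.27, SE 0.05; list adjusted p = 0.0826).

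Markers of glial, endothelial and interneuron types had list medians between -0.15 and -0.03. Microglial markers fell in 8 of 12 cases, as P2ry12 did (log2 fold change -0.20, SE 0.04), and endothelial and mural markers in 5 of 12, as Cldn5 did (-0.29, SE 0.08). Fry called both lower (adjusted p = 0.000539 and 0.001), and each had adjusted p = 0.507 with an estimated correlation. Astrocyte markers fell in 3 of 12 cases (adjusted p = 0.0267) and interneuron markers in 3 of 12 (adjusted p = 0.0199); both had adjusted p = 0.794 with an estimated correlation. Thalamic and pallidal markers, which would mark neighbouring tissue, fell in 3 of 7 cases (adjusted p = 0.000271, but adjusted p = 0.488 with an estimated correlation). Cortical glutamatergic markers included 3 genes that rose, with a negative median although the test pointed up (adjusted p = 0.466). Of 13 myelin genes 1 fell, of 8 oligodendrocyte precursor markers 1 rose, and of 8 choroid plexus markers 1 rose; no ependymal or blood gene passed. Among other lists, 2 p53 targets rose and 2 fell of 14, none of 16 interferon genes passed, 4 of 13 chaperones fell, 3 of 13 unfolded protein response genes fell and 1 rose, and 2 of 14 developmental transcription factors rose and 1 fell. Oxidative phosphorylation genes moved both ways (8 higher and 10 lower of 86), as did ribosomal proteins (3 and 3 of 76), histones (1 and 3 of 20) and mitochondrially encoded genes (0 and 2 of 13). None of these lists passed fry. The X- and Y-linked genes of the label check had 1 that rose, Tsix (0.91, SE 0.20; list adjusted p = 0.0102, adjusted p = 0.749 with an estimated correlation), which lies antisense to Xist. Hox genes were too low to be measured.

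On the deposited FPKM values, which take no account of differences in RNA composition, limma called 7802 genes, of which 80.0% were higher, against 50.8% of the edgeR calls. The median log2 fold change of all genes was 0.05 there and 0.01 in edgeR, and the medians of the direct-pathway list (0.02) and the astrocyte list (0.04) turned positive. Animals of the early-numbered codes alone (5 Q140 and 6 WT) gave 4912 called genes, of which 4381 were among the 5909. Animals of the late-numbered codes alone gave 825 called genes. The 3 Q140 animals among the late ones were male and the 2 WT animals female, so that sex and genotype were separated only by the sex term, which rested on the other late animals. Without restriction on the code, males alone (4 Q140 and 4 WT) gave 2807 against 4016 in females alone; fewer animals entered each of these fits. No gene passed the test for a difference of the knock-in effect between females and males with edgeR (1221 genes at an unadjusted p below 0.05), and DESeq2 called 2.

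**Figure D1:**
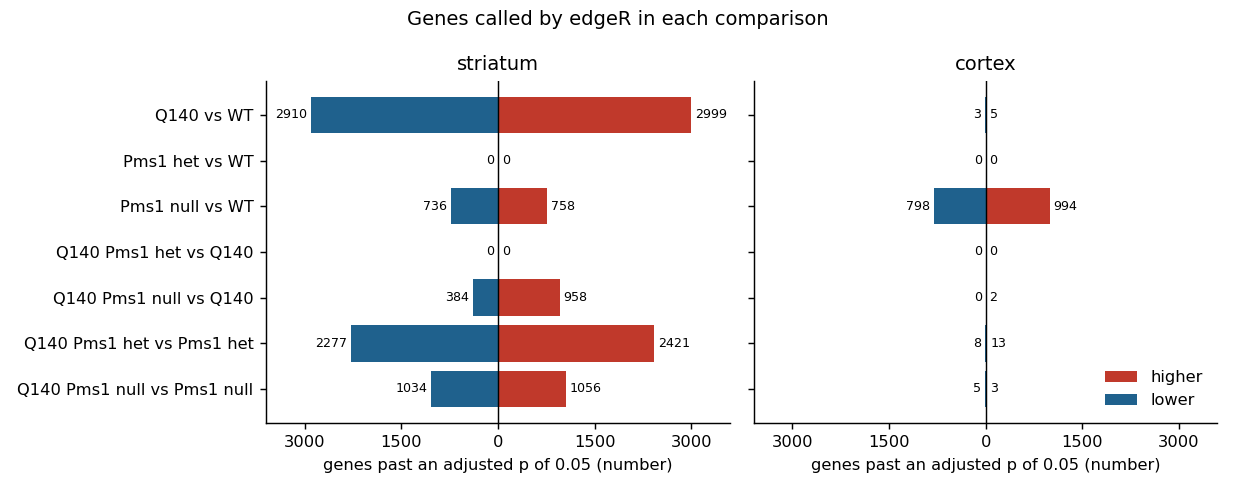
Bars to the right give the number of genes higher and bars to the left the number lower at an adjusted p of 0.05 in edgeR, for 7 comparisons in striatum and in cortex with 8 animals per genotype. Q140 against WT had 2999 higher and 2910 lower genes in striatum and 5 and 3 in cortex.

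A score summarised the striatal knock-in effect in each animal. It was the mean log2 level of the genes called in the other sex, signed by their direction and scaled so that WT averaged 0 and Q140 averaged 1. The Q140 animals had an SD of 0.0964 (n = 8). Q140 Pms1 het scored 0.917 ± 0.168 and Q140 Pms1 null 0.649 ± 0.168, with single animals of the latter between 0.445 and 0.968 (SD, n = 8 each). The difference between Q140 Pms1 null and Q140 was -0.351 (exact permutation within sex, two-sided p = 0.000816, adjusted p = 0.00229 over 14 tests). For Q140 Pms1 het it was -0.083 (exact permutation p = 0.209, adjusted p = 0.244), and -0.155 (exact permutation p = 0.0171, unadjusted) when the genes were chosen in all animals, the scored ones included. Without the knock-in, Pms1 null animals scored 0.136 ± 0.127 (SD, n = 8; exact permutation p = 0.0233 against WT, adjusted p = 0.0375) and Pms1 het animals 0.0805 ± 0.116 (SD, n = 8; exact permutation p = 0.131, adjusted p = 0.183). Set against its own Pms1 background, the knock-in effect kept 51.3% of its size in Pms1 null animals (95% bootstrap interval 41.5% to 62.0%). In Pms1 het animals it kept 83.6% (72.9% to 95.8%). The intervals hold the signature genes fixed and take animals as independent, so they may be too narrow. Since the score of Q140 Pms1 het did not differ from Q140 and edgeR called 0 genes for the Pms1 het interaction, a smaller effect with 1 copy is not established.

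**Figure D2:**
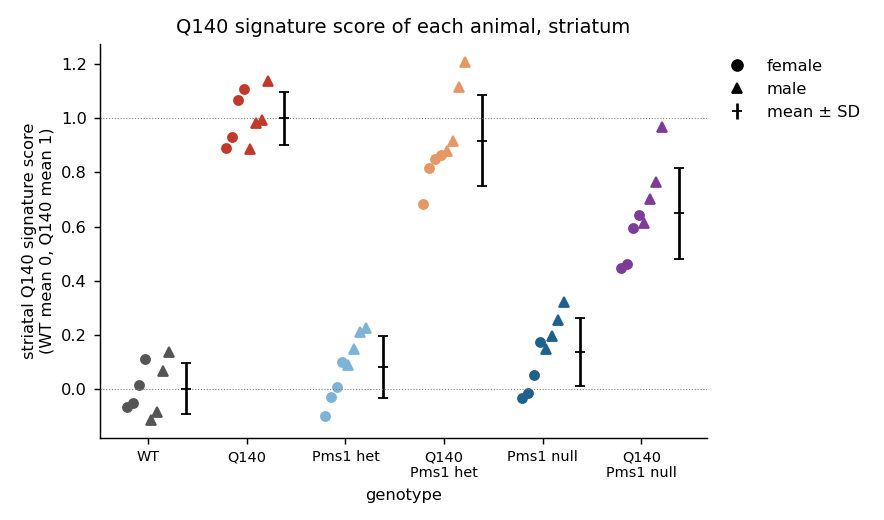
Each point is the striatal Q140 signature score of 1 animal (circles females, triangles males), with the mean and SD of the 8 animals of each genotype beside them; dotted lines mark the WT mean of 0 and the Q140 mean of 1. Q140 Pms1 null animals lay between 0.445 and 0.968 and Q140 animals between 0.887 and 1.14.

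In knock-in striatum, the loss of both Pms1 copies raised MSN genes. Compared with Q140, Q140 Pms1 null had 27 of the 30 pan-MSN genes higher and none lower, and all 30 were higher adjusted over the list alone (adjusted p = 1.4e-08, and adjusted p = 0.000299 with an estimated correlation). Ddit4l rose by a log2 fold change of 0.84 (SE 0.09), Ryr1 by 0.69 (SE 0.09) and Scn4b by 0.52 (SE 0.06). Indirect-pathway markers rose in 6 of 8 cases, 7 adjusted over the list alone (adjusted p = 7.4e-09, and adjusted p = 0.000227 with an estimated correlation), including Penk (0.42, SE 0.05), Adora2a (0.40, SE 0.06) and Drd2, the D2 dopamine receptor (0.32, SE 0.05). The ion channel and G-protein regulator list had 12 of 18 higher (adjusted p = 4.9e-06, and adjusted p = 0.00913 with an estimated correlation). Beta protocadherins went the other way, with 8 of 22 lower and 14 adjusted over the list alone (adjusted p = 3.8e-05, and adjusted p = 0.0175 with an estimated correlation).

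EdgeR called 1342 genes in this comparison, 958 higher and 384 lower; 67 differed by more than 1.5-fold, 47 higher and 20 lower. The largest increases were those of Wnt8b (log2 fold change 1.12, SE 0.32), the interleukin receptor subunit Il2rb (1.07, SE 0.16), Mafa (1.04, SE 0.18), Cpne9 (0.89, SE 0.12) and Sec14l3 (0.88, SE 0.14). The largest decreases were those of Sfmbt2 (-0.89, SE 0.10), Magel2 (-0.73, SE 0.19), the desmosomal protein gene Dsp (-0.70, SE 0.18), Enkur (-0.70, SE 0.22) and Ttn (-0.64, SE 0.13). Wt1 fell by 3.10 (SE 0.41), to 0.0919 ± 0.114 CPM (SD, n = 8), at few counts per library. Of the immediate early genes none passed: Egr2 had a mean of 10.7 ± 7.26 CPM in Q140 and 10.4 ± 7.05 CPM in Q140 Pms1 null (SD, n = 8 each). Synaptic receptors had 4 of 16 higher (adjusted p = 0.0188, but adjusted p = 0.442 with an estimated correlation). Fry also called thalamic and pallidal markers (adjusted p = 0.00708), ribosomal proteins (adjusted p = 0.0421) and mismatch repair genes (adjusted p = 0.0452). These 3 lists did not pass camera with an estimated correlation (adjusted p = 0.265, 0.469 and 0.479). The median of the synaptic list turned negative on the FPKM scale (-0.01). All Q140 Pms1 null animals carry late-numbered codes; against the 3 late-numbered Q140 animals, all male, the count was 143.

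Genes called in both the knock-in effect and the effect of Pms1 loss on it lay in opposite directions, with 1 exception. Of the 5909 genes called in Q140 against WT, 1153 were called in the opposite direction in Q140 Pms1 null against Q140, and 1 in the same direction. They made up 862 of the 2910 lowered genes and 291 of the 2999 raised genes. Independent lists of these sizes would share 209 genes in opposite directions, while in groups simulated without a Pms1 effect the second comparison called 0 genes, so that the shared count of 0 was fixed and gives no reference. Because the Q140 libraries enter both comparisons, they were also split so that 4 served each comparison, and the count was then 554 (median of 10 splits, 389 to 822), against a median of 1.5 in the same direction.

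The knock-in effect was then measured on each Pms1 background with its own controls, which share no library with Q140 and WT. On the Pms1 het background, 29 of 30 pan-MSN genes fell (adjusted p = 1.8e-13, and adjusted p = 0.000529 with an estimated correlation) and 17 of 22 beta protocadherins rose (adjusted p = 8.5e-12, and adjusted p = 0.00258 with an estimated correlation). On the Pms1 null background, 20 of 30 pan-MSN genes fell (adjusted p = 2.7e-06, and adjusted p = 0.0179 with an estimated correlation) and 16 of 22 beta protocadherins rose (adjusted p = 2.1e-08, and adjusted p = 0.00194 with an estimated correlation). Penk fell by 0.87 on the log2 scale in Q140 Pms1 het against Pms1 het (SE 0.05) and by 0.63 in Q140 Pms1 null against Pms1 null (SE 0.05).

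**Figure D3:**
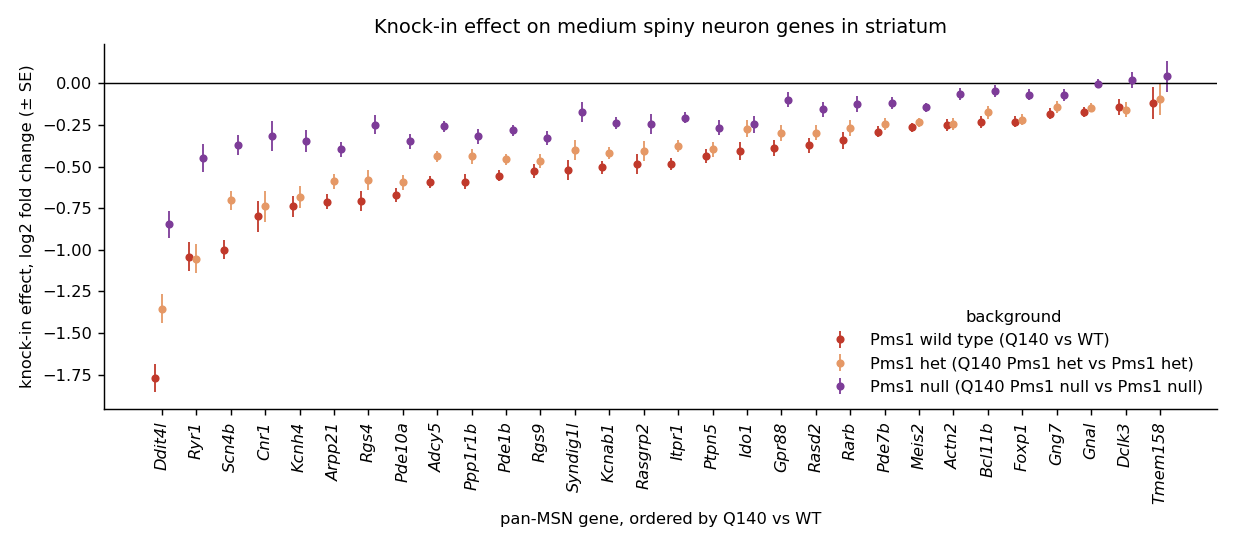
Points are the log2 fold changes of the knock-in effect on 30 pan-MSN genes in striatum (bars, SE), measured on the Pms1 wild-type, Pms1 het and Pms1 null backgrounds with 8 animals per genotype. Of the 30 genes, 29, 29 and 20 fell on the 3 backgrounds, and the point for Scn4b lies at -1.0, -0.70 and -0.37.

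In Q140 Pms1 het against Pms1 het, edgeR called 4698 genes, 2421 higher and 2277 lower. The leading genes included Ttn (log2 fold change 1.1, SE 0.14), Rprm (1.05, SE 0.12), Fam196b (0.97, SE 0.15) and Sfmbt2 (0.95, SE 0.10) among those raised, and Aoah (-1.88, SE 0.25), Mafa (-1.66, SE 0.17), Gpx6 (-1.52, SE 0.14), Cpne9 (-1.49, SE 0.11) and Dgat2l6 (-1.48, SE 0.17) among those lowered. Of the 5909 genes of Q140 against WT, 3425 were called in the same direction here (735 if the lists were independent), and over all 5909 genes the fold change had a median of 0.71 of its size in Q140 against WT. This ratio is biased downwards, because the genes were selected by their change in Q140 against WT; the score, with genes chosen in the other sex, kept 83.6%. Fry called 16 of 31 lists and camera with an estimated correlation 5. Immediate early genes fell in 7 of 15 cases (adjusted p = 0.0095, but adjusted p = 0.646 with an estimated correlation). Oxidative phosphorylation genes rose in 18 of 86 cases (adjusted p = 0.0312, but adjusted p = 0.653 with an estimated correlation).

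In Q140 Pms1 null against Pms1 null the count was 2090 genes, 1056 higher and 1034 lower. Of the 5909 genes, 1578 were called in the same direction (327 if independent), and the median ratio of fold changes over all 5909 was 0.40, with the same bias, beside 51.3% for the score. The genes that fell most were Egr2 (log2 fold change -1.34, SE 0.29), Aoah (-1.32, SE 0.23), the serine protease gene Tmprss6 (-1.18, SE 0.20), Nr4a3 (-1.15, SE 0.33) and Dgat2l6 (-1.05, SE 0.16). Slitrk6 rose (0.73, SE 0.14). The other 4 leading increases had spreads as large as their means: Rmrp, the RNA of RNase MRP (1.95, SE 0.50), Rpph1, the RNA of RNase P (1.66, SE 0.50), Mir6236 (1.28, SE 0.41) and Lars2, a mitochondrial leucyl-tRNA synthetase (1.12, SE 0.33). Rmrp stood at 1.67 ± 2.23 CPM in Q140 Pms1 null (SD, n = 8), and Lars2 at 244 ± 273 CPM. Animal 44-1 alone had 7.12 CPM of Rmrp and 910 CPM of Lars2. Without TMM scaling that library also held 10565 CPM of Gm42418, a predicted gene named after its values were seen. The cortical library of animal 7-3 was likewise high in both, with 7354 CPM of Gm42418 and 735 CPM of Lars2. Whether the Lars2 gene itself changed was not tested. Fry called 8 of 31 lists and camera with an estimated correlation 3. Immediate early genes fell in 7 of 15 cases and astrocyte markers in 5 of 12, and both had adjusted p = 0.00278 (adjusted p = 0.229 with an estimated correlation). Mismatch repair genes rose in 3 of 17 cases (adjusted p = 0.00278, but adjusted p = 0.235 with an estimated correlation). The ion channel and G-protein regulator list and the neurotrophin list fell (adjusted p = 0.000474 and 0.000184, but adjusted p = 0.138 each with an estimated correlation).

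Differences between backgrounds were tested directly. For Pms1 null, edgeR called 954 genes whose knock-in effect differed from that with 2 Pms1 copies, 637 with a positive and 317 with a negative difference. The knock-in effect on Ddit4l differed by 0.92 (SE 0.12), on Scn4b by 0.63 (SE 0.08), on Penk by 0.45 (SE 0.08) and on Adora2a by 0.44 (SE 0.08), in each case a smaller decrease on the null background. Sfmbt2 had a difference of -0.91 (SE 0.14), a smaller increase. Egr2 had a difference of 0.50 that did not pass the test (SE 0.41, adjusted p = 0.54). For Pms1 het, edgeR called 0 genes at this threshold (1619 at an unadjusted p below 0.05), and DESeq2 called 12. Comparing Q140 Pms1 het directly with Q140, edgeR called 0 genes (1026 at an unadjusted p below 0.05) and DESeq2 called 1. Adjusted over the list alone, 3 of 22 beta protocadherins were lower in that comparison (fry adjusted p = 0.0682).

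Without the knock-in, the loss of both Pms1 copies left all 30 pan-MSN genes short of the test's threshold. In Pms1 null striatum, Plin4 (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803), a lipid droplet protein, rose from 4.91 ± 2.73 to 23.3 ± 17.2 CPM (SD, n = 8 each; log2 fold change 2.06, SE 0.48, adjusted p = 0.00666). The phospholyase gene Etnppl (1.04, SE 0.27), the hypoxia-inducible factor Hif3a (0.97, SE 0.22), the arrestin-related Arrdc2 (0.95, SE 0.23) and the sulfotransferase Sult1a1 (0.88, SE 0.17) followed; all 5 respond to glucocorticoids. Gabra2 (ENSMUSG00000000560, chromosome 5, 70957597 to 71095849), a GABA-A receptor subunit, fell the most (-0.84, SE 0.16), followed by the Wnt pathway genes Dkk2 (-0.75, SE 0.19) and Fzd10 (-0.72, SE 0.20), the phosphatase Dusp4 (-0.68, SE 0.15) and Slc38a5 (-0.67, SE 0.15). EdgeR called 1494 genes, 758 higher and 736 lower, and 78 differed by more than 1.5-fold, 65 higher and 13 lower. No MSN list passed: of the pan-MSN, indirect-pathway and direct-pathway lists, none had a fry call. Unfolded protein response genes fell in 3 of 13 cases, 4 adjusted over the list alone (adjusted p = 0.00288, but adjusted p = 0.331 with an estimated correlation). P53 targets rose in 3 of 14 cases and synaptic receptors fell in 2 of 16 (both adjusted p = 0.0262, but adjusted p = 0.61 with an estimated correlation).

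In Pms1 null cortex, Plin4 (log2 fold change 1.88, SE 0.44), Etnppl (0.90, SE 0.21), Hif3a (0.90, SE 0.20), Wdfy1 (0.73, SE 0.17) and the collagen gene Col5a3 (0.70, SE 0.12) led the increases. Gabra2 (-0.85, SE 0.17), the neuropeptide gene Cort (-0.78, SE 0.17), Klf10 (-0.66, SE 0.14), the olfactory receptor gene Olfr464 (-0.62, SE 0.20) and Fabp7 (-0.62, SE 0.13) led the decreases. The levels of Gabra2 and Wdfy1 varied in steps between animals of one genotype. Htt rose slightly (0.09, SE 0.03, adjusted p = 0.0468). EdgeR called 1792 genes, 994 higher and 798 lower, and 103 differed by more than 1.5-fold, 86 higher and 17 lower. Unfolded protein response genes fell in 3 of 13 cases and endothelial and mural markers in 4 of 12 (adjusted p = 0.00215 and 0.0112, but adjusted p = 0.279 and 0.434 with an estimated correlation). Of 17976 genes measured in both tissues, 566 were called in both in the same direction and 1 in opposite directions, from 1477 striatal and 1771 cortical calls; independent lists would share 72.8. The tissues share their animals, so these are not independent comparisons.

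Every Pms1 null animal carried a late-numbered code, against 2 of 8 WT animals. A term for early or late code reduced the calls to 473 in striatum and 293 in cortex, and late-numbered animals alone, whose 2 WT animals were both female, gave 106 and 336. With a glucocorticoid gene score as a covariate, an alternative chosen after the data were seen, striatum gave 351. The loss of 1 Pms1 copy gave 0 calls with edgeR in either tissue (1882 genes in striatum and 1938 in cortex at an unadjusted p below 0.05), and DESeq2 called 17 and 36.

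In cortex the knock-in changed few genes. Compared with WT, edgeR called 8 of 18711 genes (1369 at an unadjusted p below 0.05), 5 higher and 3 lower, and DESeq2 called 14. They were Gm2420 (log2 fold change 4.27, SE 0.42), Abhd1 (1.17, SE 0.16), Abca8a (0.37, SE 0.07), Cgref1 (0.36, SE 0.06) and Mrpl33 (0.27, SE 0.05), which rose, and Gem (-0.65, SE 0.13), Atraid (-0.26, SE 0.05) and Rgs4 (-0.14, SE 0.03), which fell; Gm2420 falls outside the naming rule and was named after its value was seen. The cortex had 5 of its 8 calls within 5 Mb of Htt (5 of 142 genes there against 3 of 18505 elsewhere; odds ratio 223, Fisher's exact test p = 1.3e-09, adjusted p = 3.7e-08). These were Gm2420, Abhd1, Cgref1, Mrpl33 and Atraid. In striatum, 63 of 144 genes near Htt were called against 31.2% elsewhere (odds ratio 1.71, Fisher's exact test p = 0.00204, adjusted p = 0.0143). No comparison had an excess of calls near Pms1. Without the choroid-rich libraries of animals 7-3, 22-3 and 17-2, 4 of the cortical genes were called.

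Immediate early genes did not pass over all genes in Q140 cortex, but 12 of 15 were lower adjusted over the list alone (fry adjusted p = 0.0419, but adjusted p = 0.0739 with an estimated correlation). Arc had a log2 fold change of -0.92 (SE 0.23, adjusted p = 0.247) and Fos of -0.81 (SE 0.27, adjusted p = 0.394). No MSN list, glial list or other list passed fry there. On the Pms1 het background edgeR called 21 cortical genes, 13 higher and 8 lower, and DESeq2 217. Abhd1 (1.39, SE 0.16), Rsph1 (0.53, SE 0.11) and Mrpl33 (0.39, SE 0.05) rose, and Fmnl1 (-0.27, SE 0.05) and Gjc3 (-0.25, SE 0.06) fell. Neurotrophin, unfolded protein response and mismatch repair lists had fry calls there (adjusted p = 0.0018, 0.0183 and 0.0183, but adjusted p = 0.104, 0.2 and 0.259 with an estimated correlation), with no member passing over all genes. Using the 2 genotypes alone, that count was 70, and without the sex term 13. On the Pms1 null background the 8 genes were Gm2420, Abhd1 (0.91, SE 0.16) and Mrpl33 (0.24, SE 0.05), which rose, and Gem (-0.71, SE 0.13), Itih3 (-0.37, SE 0.06), the glutamine synthetase gene Glul (-0.17, SE 0.04), Gm37069 and Gm37885, which fell; the predicted genes were named after their values were seen. DESeq2 called 17, the fit of the 2 genotypes alone 1, and the fit without the choroid-rich libraries 3.

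Loss of both Pms1 copies in knock-in cortex gave 2 calls with edgeR, Dgkq (log2 fold change 0.18, SE 0.03) and Gm12258 (0.26), the latter named after its value was seen, while 2713 genes had an unadjusted p below 0.05 and DESeq2 called 167. For Q140 Pms1 het against Q140, edgeR called 0 cortical genes (1065 at an unadjusted p below 0.05) and DESeq2 0. The tests of a different knock-in effect on the 2 Pms1 backgrounds called 0 cortical genes for Pms1 null (1020 at an unadjusted p below 0.05; DESeq2 0) and 0 for Pms1 het (1525; DESeq2 0). The difference between the sexes called 5 with edgeR and 68 with DESeq2. The 5 were Sorbs2 (-0.36, SE 0.06), Marcksl1 (0.65, SE 0.12), 2210011C24Rik (a negative difference), Ypel1 (0.44, SE 0.09) and Gng7 (0.28, SE 0.06), female minus male, all named after their values were seen. A cortical knock-in score could not be formed as planned. The Q140 animals did not differ from WT on genes chosen in the other sex (mean difference 0.0228 in log2 units, exact permutation p = 0.557, adjusted p = 0.557), and no retained share was computed. In these units Q140 Pms1 null lay 0.0936 above Q140 (exact permutation p = 0.011, adjusted p = 0.0257) and Q140 Pms1 het 0.081 above it (exact permutation p = 0.0167, adjusted p = 0.0335). With genes chosen in all animals these differences turned to -0.0162 and -0.149. Q140 Pms1 het lay 0.140 above Pms1 het (exact permutation p = 0.000408, the smallest possible, adjusted p = 0.00143). Q140 Pms1 null lay 0.0702 above Pms1 null (exact permutation p = 0.0241, adjusted p = 0.0375). With 500 genes, Q140 minus WT was -0.0148 in females and -0.00284 in males. Since Q140 and WT did not differ on the score, differences between the other genotypes do not show a stronger or weaker knock-in effect.

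The knock-in effect differed between striatum and cortex in 2617 of 19723 genes, with 977 more positive and 1640 more negative in striatum. The difference was -1.04 for Scn4b (SE 0.09), -0.78 for Penk (SE 0.10), -0.63 for Drd1 (SE 0.08) and 1.39 for Sfmbt2 (SE 0.15). It did not pass for Egr2 (-0.69, SE 0.44, adjusted p = 0.36) or Fos (0.32, SE 0.44, adjusted p = 0.74). Of the 8 cortical calls of Q140 against WT, 6 were called in striatum in the same direction. Gm2420 had a striatal log2 fold change of 5.18 (SE 0.32) and Abhd1 of 0.75 (SE 0.12).

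**Figure D4:**
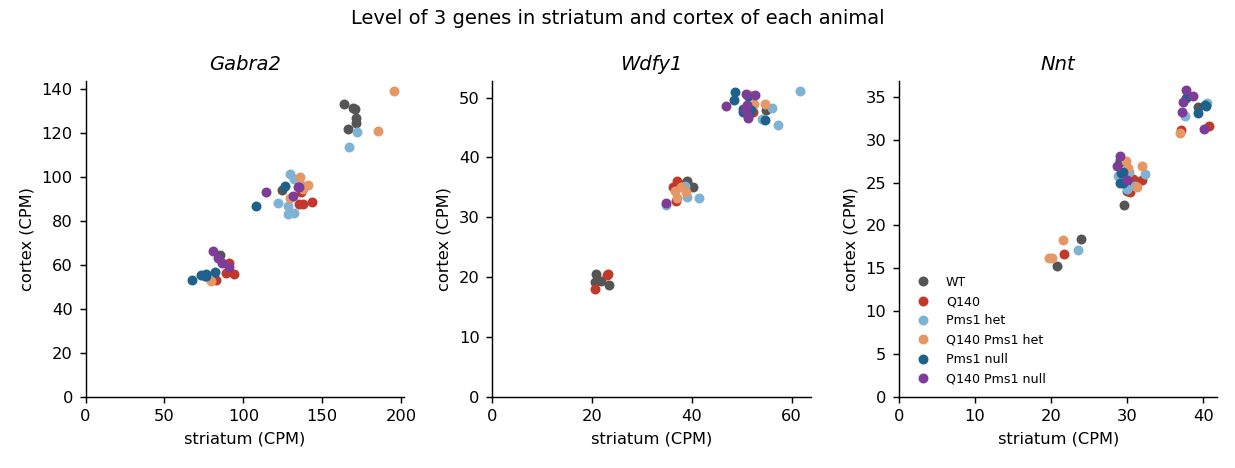
Each point is 1 of 48 animals, placed by its level of Gabra2, Wdfy1 or Nnt in striatum (CPM, horizontal axis) and in cortex (CPM, vertical axis) and coloured by genotype. The levels of each gene fell into 3 steps, and animals of one genotype lay on different steps; Gabra2 and Wdfy1 are named above, and Nnt was chosen after its values were seen.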

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

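The tests of Htt RNA and of glucocorticoid genes below were chosen after the data were seen; the other tests were set before their results. Pms1 null and WT differed in 1494 striatal and 1792 cortical genes, while every Pms1 null animal carried a late-numbered code. If the code marked a cohort that caused this, the late minus early contrast in 24 other animals should move the called genes alike, but its slope on the Pms1 null fold change was -0.0133 in striatum (95% interval -0.246 to 0.211) and 0.137 in cortex (-0.131 to 0.398), below the 0.5 set beforehand, with only 4 late animals among the 24. Those 4 were all male, with first numbers from 18 to 23, while the Pms1 null animals included 4 females and numbers up to 44. For males with such numbers this argues against the cohort as the whole cause. It cannot speak for late females or for higher numbers. A part stays open in cortex, where 69.2% of the called genes had the same sign in that contrast (47.4% in striatum). Over these genes the slope of the Pms1 het on the Pms1 null fold change was 0.286 in striatum (0.2 to 0.379). In cortex it was 0.155 (0.0606 to 0.327). For the slope the WT animals were split so that none served both fold changes, but the genes had been chosen with all of them. In the resampling for the interval, 1 WT animal could also serve both. A positive slope could thus arise without any effect in Pms1 het animals, so it cannot decide whether Pms1 copies have a graded effect. A glucocorticoid-responsive state of the Pms1 null animals stays open: slopes of 1.2 (0.401 to 1.59) and 1.07 (-0.0516 to 1.52) on the predicted change cannot be told apart from a slope under 0.5. The predicted change came to a share of 0.230 of the observed one in striatum and 0.126 in cortex, with the predicted sign in 66.7% and 60.8% of genes, so such a state may account for a part. Of the 18 list genes, 5 (Plin4, Etnppl, Hif3a, Arrdc2 and Sult1a1) were listed after their changes were seen. Without these 5 the shares were 0.196 and 0.0622, with the predicted sign in 64.8% and 52.4% of genes. The count of 473 striatal genes with the code term leaves part of the difference that cohort and genotype cannot separate.

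The striatal score was lower in Q140 Pms1 null than in Q140 animals. All 8 Q140 Pms1 null animals but only 3 of 8 Q140 animals, all male, carried late codes. Late Q140 males (n = 3, mean 1.04) scored 0.275 above Q140 Pms1 null males (n = 4, mean 0.762), which met the bound set beforehand against the cohort as the whole cause (exact permutation p = 0.0571, smallest possible 0.0286), on few animals taken as independent. Males with first number 18 lay closer together, at 1.14 and 0.993 in Q140 and 0.968 in Q140 Pms1 null, so a part of the difference may go with the codes. Htt RNA, counted over both alleles, was higher rather than lower (log2 fold change 0.0895), which argues against less total Htt transcript as the cause. The alleles were not told apart, so a fall of the Q140 transcript alone cannot be excluded. Regression of the shared Q140 libraries is argued against by the retained share of 0.513 (0.415 to 0.620). Its numerator compares Q140 Pms1 null with Pms1 null; the Q140 and WT libraries enter its denominator, and the interval resamples them. With the Q140 libraries split so that no library served both comparisons, a median of 554 genes moved in opposite directions and 1.5 in the same direction. A weaker action of the expanded allele without Pms1 may account for the lower score; the length of the repeat was not measured here.

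The effect of the knock-in differed between the tissues in 2617 genes, between the Pms1 null and wild-type backgrounds in 954 striatal genes, and between the sexes in 5 cortical genes, each by a test of the difference. Single animals stood apart in 8 of 84 groups of 8, where chance gives about 1 in 20, or 4.2. Choroid plexus markers had a mean log2 CPM of 4.41 in the cortex of Q140 animal 7-3, 4.10 in Pms1 null animal 22-3, 3.87 in Q140 Pms1 null animal 17-2 and 1.28 in the striatum of Pms1 null animal 43-3. Blood genes had -0.142 in the striatum and -0.616 in the cortex of Pms1 het animal 5-3. Among the Pms1 null striatal libraries, Pms1 was lowest in animal 22-3 (3.08 CPM). Among the WT cortical libraries, Htt was lowest in animal 14-2 (209 CPM).

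Groups were redrawn in 100 splits of the same animals, the real one included, and tested with limma on log2 CPM; the count is how many splits gave as many genes. In striatum it was 1 of 100 for Q140 against WT (5858 genes, highest other split 4164), for Pms1 null against WT (1496, highest other 685), for Q140 Pms1 null against Q140 (1337, highest other 691), for Q140 Pms1 het against Pms1 het (4787, highest other 2048) and for Q140 Pms1 null against Pms1 null (2142, highest other 835). It was 2 of 100 for the difference on the Pms1 null background (969, highest other 1002). In cortex it was 1 of 100 for Pms1 null against WT (1847, highest other 168) and for Q140 Pms1 het against Pms1 het (29, highest other 1), 3 of 100 for Q140 against WT (8, highest other 80), 4 of 100 for Q140 Pms1 null against Pms1 null (9, highest other 35) and 4 of 100 for the difference between the sexes (5, highest other 15). It was 1 of 100 for the tissue difference (3527, highest other 2182). Each of these counts lay under a share of 0.05 if animals are independent, without adjustment for the number of results tested. Where the count was 2 to 4 of 100, other splits gave as many genes or more, so chance stays open there. The splits ignore that animals sharing a first number correlated by 0.133 in striatum and 0.131 in cortex and that 3 Pms1 null animals share 1 number. With that correlation modelled, voom called 935 striatal and 1096 cortical genes for Pms1 null against WT. In addition, splits of the cortical Q140 and WT animals with up to 80 genes point to structure among the samples.

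Chance could not be excluded for Q140 Pms1 null against Q140 in cortex, with 6 of 100 splits (2 genes, highest other 585, which points to structure among the samples). Where the real split gave 0 genes, any split gives as many, so the count of 100 of 100 was fixed and decides nothing. In striatum these were Pms1 het against WT (highest other 322), Q140 Pms1 het against Q140 (2), the difference on the Pms1 het background (1) and that between the sexes (18). In cortex they were Pms1 het against WT (62), Q140 Pms1 het against Q140 (3), and the differences on the Pms1 null (5) and Pms1 het (1) backgrounds.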

How the results depend on the processing

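The late- or early-code fits, the fits without single libraries, the glucocorticoid covariate, the shorter glucocorticoid list and the unscaled cortical score were chosen after the data were seen. Of 188 alternative values of the results, 148 kept their direction and their side of the threshold, or a count within 1.5 times, and 40 did not. A count within 1.5 times does not say that the same genes were called or in which direction. The FPKM fit of striatal Q140 against WT was kept by that rule. It called 7802 genes, 80.0% of them higher, and shared 4552 with the 5909 of edgeR, of which 50.8% were higher. Of 1322 values of named genes under RLE size factors, DESeq2 and no sex term, 47 no longer passed and 0 reversed. The causes of the changes below were not tested, except that fits on fewer animals have fewer samples. Pairing by animal (the animal as a block) gave 3579 genes for the tissue difference against 2617, with 2587 called in both; it bears on no other result. With RLE size factors, fry called 6 rather than 8 lists in striatal Q140 Pms1 null against Q140, 17 rather than 16 in striatal and 4 rather than 3 in cortical Q140 Pms1 het against Pms1 het, and 1 rather than 0 in cortical Q140 Pms1 null against Q140; the other 10 counts of lists were equal.

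For Pms1 null against WT in striatum (1494) the count was 984 with no low-count filter, 990 from the 2 genotypes alone, 473 with a term for early or late codes (418 shared with the 1494), 106 in late codes alone (75 shared), 935 with voom and correlated codes, and 351 with the glucocorticoid covariate. In cortex (1792) it was 1174, 293, 336, 1096 and 1126 with no filter, the code term, late codes, voom and the covariate. Striatal Q140 against WT (5909) fell to 825 in late codes (3 male Q140 and 2 female WT animals) and 2807 in males, and Q140 Pms1 null against Q140 (1342) to 143 in late codes (128 shared); with the code term it was 951. In cortex, Q140 against WT (8) gave 0 in late codes, 4 without the libraries of 7-3, 22-3 and 17-2, 1 in males and 14 with DESeq2. Q140 Pms1 null against Q140 (2) gave 0 from the 2 genotypes, with the code term and in late codes, and 167 with DESeq2. Q140 Pms1 het against Pms1 het (21) gave 70 from the 2 genotypes, 13 with no sex term and 217 with DESeq2, and Q140 Pms1 null against Pms1 null (8) gave 1 from the 2 genotypes, 3 in late codes, 3 without the 3 libraries and 17 with DESeq2.

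Of the counts of 0, striatal Q140 Pms1 het against Q140 gave 1 with no filter, 1 without 14-4 and 44-1 and 1 with DESeq2. Pms1 het against WT gave 1 from the 2 genotypes and 17 with DESeq2 in striatum, and 36 with DESeq2 in cortex. DESeq2 gave 12 for the striatal difference on the Pms1 het background, 2 for that between the sexes in striatum and 68 in cortex (5). The 1153 striatal genes that moved back became 554 with the Q140 libraries split. With genes chosen in all animals, the cortical score differences turned to -0.0162 (Q140 Pms1 null) and -0.149 (Q140 Pms1 het), the striatal retained shares were 40.4% and 69.7%, and the striatal score difference of Q140 Pms1 het from Q140 was -0.155 (exact permutation p = 0.0171, unadjusted) rather than -0.083; these genes were chosen partly in the animals scored. Animals that share the first number of their code correlated by 0.133 in striatum and 0.131 in cortex. Depth limited low genes: Wt1 was near 0.0904 CPM in WT.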

Other observations

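The tests of the genes near Htt and of discrete levels, and the glucocorticoid list, were chosen after the data were seen. The mean log2 level of 18 genes that glucocorticoids induce was 0.593 above WT in Pms1 null striatum (exact permutation p = 0.00531, adjusted p = 0.0318; 14 of 18 genes called higher) and 0.429 above it in cortex (exact permutation p = 0.011, adjusted p = 0.0331; 7 called higher). Q140 Pms1 null animals differed from Q140 by -0.0308 in striatum (exact permutation p = 0.851, adjusted p = 0.851). Most of the difference came from females, which averaged 0.934 in striatum and 0.696 in cortex against 0.252 and 0.162 in males. The list held 5 genes chosen for their rise in these animals. Without them the mean of the other 13 was 0.404 above WT in striatum (exact permutation p = 0.00327, adjusted p = 0.0196; 9 called higher) and 0.247 in cortex (exact permutation p = 0.0188, adjusted p = 0.0563; 2 called higher). These tests treat animals as independent, but 3 of the 4 Pms1 null females share a first code number, as do 2 of the 4 males. With animals that share a number averaged, 5 units against 5, the 13 genes differed by 0.383 in striatum (exact permutation p = 0.05, adjusted p = 0.1) and 0.236 in cortex (exact permutation p = 0.15, adjusted p = 0.15; smallest possible 0.0167), which did not pass. A common rise of these genes is therefore not established.

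No test of the blood or myelin list passed in cortex. All 5 blood genes were higher in cortex of Q140 Pms1 het than of Pms1 het adjusted over the list alone, with a median log2 fold change of 2.55 (fry adjusted p = 0.184). Single animals weighed on this. Without TMM scaling, Hbb-bs had 29.7 CPM in Q140 Pms1 het animal 12-1 and 11.2 CPM in 20-2. The next highest animal of that genotype, 9-4, had 3.93 CPM, and the lowest, 13-1, had 0.150 CPM. Adjusted over the list alone, 7 of 13 myelin genes were lower in the same comparison (fry adjusted p = 0.0522) and 7 in Q140 Pms1 null against Q140 (fry adjusted p = 0.124).

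Sequence variants may lie behind some of the called genes. Called neighbours of Htt in cortex kept a mean of 0.845 of their fold change on the other Pms1 backgrounds (0.583 to 1.11 at 2 SE either side, over genes and not animals). Variants or sequence linked to the knock-in allele would give this. A response to the allele itself would persist as well, so the ratio cannot separate the explanations. Cortical calls were also in excess near Htt on the Pms1 het background (odds ratio 42.1, Fisher's exact test adjusted p = 6.2e-06). On the Pms1 null background the odds ratio was 79.7 (Fisher's exact test adjusted p = 0.00022), from 3 called genes near Htt. This argues against a response spread evenly over the genome for these calls. It does not separate linked variants from a response confined to genes near the allele. Gm2420 lies 2.11 Mb from Htt (chromosome 5, 32720330 to 32736194, GRCm38). Levels of Gabra2 (chromosome 5, 70957597 to 71095849), Wdfy1 (chromosome 1, 79702262 to 79776143) and Nnt (chromosome 13, 119335448 to 119408997) each put 48 of 48 animals in the same of 3 classes in both tissues (permutation p = 1e-05 each, the smallest possible). Ide matched in 34 with 3 classes and in 48 with 2 classes (permutation p = 1e-05), with 12 animals in its high class, 0 of them Pms1 null or Q140 Pms1 null. The high class of Wdfy1, on the chromosome of Pms1, held 1 of 8 WT, 4 of 8 Pms1 het and 8 of 8 Pms1 null animals. That of Gabra2, on the chromosome of Htt, held 6 WT, 0 Q140 and 0 Pms1 null animals. It also held 2 Pms1 het and 2 Q140 Pms1 het animals. Nnt and Ide (chromosome 19) lie on other chromosomes than Pms1 and Htt, so physical linkage to a targeted allele does not apply to them. WT and Pms1 null animals both lack the knock-in. The low class of Gabra2 held 1 WT and 6 Pms1 null animals, so linkage to the Q140 allele cannot account for that difference. For Wdfy1, and for Gabra2 in knock-in animals, background variants and variants linked to a targeted allele cannot be told apart. No genotype was read.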
